A study of Mus musculus with 8 samples.

How the data were processed

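The deposited values are a signal per gene, reads per gene divided by 1 size factor per library, for 24015 gene symbols in 8 libraries. The submitters' processing notes name TopHat2 2.0.11, HTSeq 0.6.1 and DESeq (version not given), without saying what each was used for, and the mouse genome mm9. The gene annotation, the strand of the libraries and the medium components are not given in the sources used here. Total RNA was prepared with the RNeasy Plus Mini Kit and sequenced from standard Illumina libraries. Every column of values was used, and no library was left out of the fits.

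Each library's values step in units of 1 read, so whole reads were recovered by dividing by that step, and 100% of values were whole within 0.01 reads. Values were log2-transformed after adding 1, and genes with at least 10 normalized counts in at least 2 of 8 libraries were kept, 13527 of them. Differences between times were estimated with limma 3.58.1 (trend) over all 8 libraries at once, with 4 residual degrees of freedom and 8.16 prior ones, and p-values were adjusted by the Benjamini-Hochberg method, with calls at adjusted p below 0.05. Errors given with fold changes are standard errors of this fit, and errors given with levels are standard deviations over n = 2 libraries. Counts quoted for groups use the adjustment over all tested genes, followed in brackets by higher and lower counts adjusted over the list alone. On the recovered reads, edgeR 4.0.16 (quasi-likelihood) called 7581, 9633, 8055, 7167, 4820 and 1361 genes for day 7, 14 and 21 against day 0, day 14 against 7, day 21 against 14 and day 21 against 7, and DESeq2 1.42.0 called 6642, 8841, 7187, 6157, 3963 and 1193. R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were used.

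Gene lists covering bone, cartilage, fat, fibroblast and other cell identities, matrix, cell cycle, metabolism, immunity, signalling and stress were written from general knowledge, 34 in all, and fixed before the data were examined, as were the filter, the threshold, the 6 comparisons and most alternatives. Lists with at least 5 tested members, 31 of them, were tested with limma's camera at a preset correlation between genes of 0.01 and adjusted over the 31. The same test was repeated with the correlation between genes estimated from these libraries, which called 0 lists in every comparison. That version also takes its p-values from a distribution with 4 degrees of freedom, so its losses do not measure correlation alone. In the text the first adjusted p of a list is from the preset correlation. The read floor of list medians is that used for genes with 0 reads. List medians weigh members alike, whereas the test compares members with all other genes, so a median, a mean and the direction of the test can differ in sign.

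Genes named in the text follow a rule. Per comparison these are the 10 largest rises and 10 largest falls among called genes with a mean of at least 50 in the higher group and no overlap between the libraries, without predicted gene models, plus up to 4 called members with the largest change and up to 2 uncalled members per list. Runx2, Sp7, Alpl, Bglap, Ibsp, Spp1, Dmp1, Enpp1, Ank, Mgp, Col1a1, Acta2, Postn, Pdgfra, Tcf21, Fkbp5, Sox9 and Pparg were always considered. Genes with 0 reads over a group are given as at least a fold, with a floor of 3 reads over that group, and genes with 1 to 3 reads as a ratio with a 95% counting interval. Such intervals cover counting error only, not differences between cultures.

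Transcript length and GC content came from GENCODE M21, matched by symbol for 23640 genes (98.4%), 22709 directly and 931 through a single RefSeq synonym. That annotation sits on GRCm38 and not mm9, so no coordinates were used. Reads of near-identical genes can be assigned to the wrong member, which bears on Lyz2 and Lyz1, the Serpina3 and Fmo families, and ribosomal protein genes with their pseudogenes. With the strand unknown, values of genes that overlap others on the opposite strand are uncertain.

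The fits were tried on simulated data with known changes. Between days 7 and 0 limma recovered 60.6% of 66 genes altered 1.5-fold, 90.4% of 73 altered 2-fold and 100% of 61 altered 4-fold, with 8 of 13112 unaltered genes called. For days 21 and 7 the shares were 59.1, 91.8 and 100%, with 9 of 13117 unaltered genes called, and 0 of 31 lists was called without a planted change. Far fewer genes were altered than were called in the data, and simulated genes varied independently of each other. The simulation therefore does not test list calls at the correlations estimated for real lists, which reached 0.93 for ribosomal protein genes. Removal of the length and GC trend returned 1.94 for a planted log2 change of 2, in genes drawn without regard to length. A planted slope of -0.50 went to 0, which the removal gives for any data, so that is no check. Whether a change shared by long or by short transcripts survives the removal was not simulated.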

Results

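RNA sequencing followed gene expression in cardiac fibroblasts of wild-type C57BL/6J mice kept in osteogenic differentiation medium, which is meant to turn mesenchymal cells into bone-forming cells. Fibroblasts were harvested before the medium (day 0) and after 7, 14 and 21 days in it, with 2 libraries at each time and 8 in all. Reads assigned to genes numbered 21883498 and 13399313 at day 0, 19399248 and 20225968 at day 7, 19199575 and 14932213 at day 14, and 17507952 and 19522382 at day 21. Between 15409 and 16200 genes were detected per library, and the 10 genes with the most reads held 10.3 to 13.6% of the signal. Fibronectin (Fn1) had the most reads of any gene at day 0 and the acute-phase gene Serpina3n at every later time, with no correction for transcript length. Of 24015 gene symbols, 5936 had no read in any library and 13527 entered the tests.

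Time in the medium separated the libraries far more than replication did. None of the libraries comes from cells kept for 7 to 21 days without the medium. Differences from day 0 therefore do not separate an effect of the medium from that of days in culture. The first principal component held 75.7% of the variance and placed day 0 at -106 and -105, day 7 at 16.3 and 13.2, day 14 at 50 and 55.7, and day 21 at 37.1 and 38.4. The second component (13.0%) set the day 14 libraries (22.8 and 48.6) against day 7 (-30.5 and -30.6), with day 21 between them (-8.36 and -19.8). Replicate libraries correlated at 0.993, 0.994, 0.988 and 0.990 from day 0 to day 21. Their differences exceeded counting error by chi-square over degrees of freedom of 5.12, 3.61, 20.1 and 19.6, so days 14 and 21 were the noisier times. The sample labels do not say whether the 2 libraries of a time came from separate cultures or animals, and the p-values measure only the spread between these samples. Lists were tested with camera of limma, at a preset correlation between genes and again with an estimated one. Every gene given below as called had both libraries of one time above or below both of the other.

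**Figure D1:**
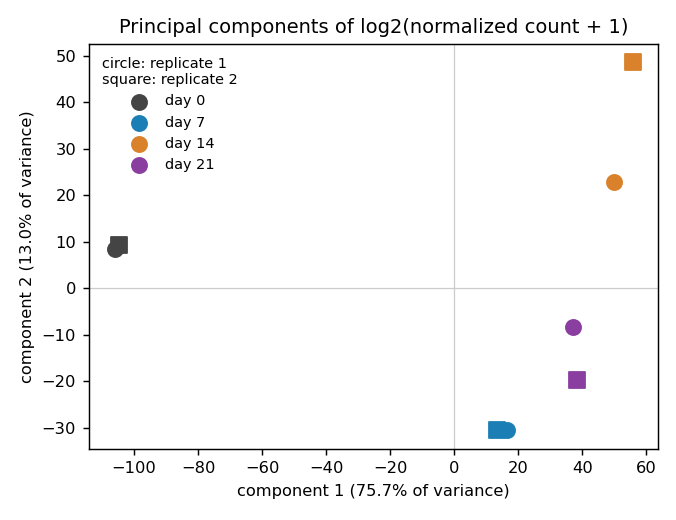
Principal components 1 and 2 of log2 normalized counts, 1 point per library, coloured by day in the medium.

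After 7 days the genes that define osteoblasts had not moved together. Sp7, the transcription factor that commits cells to the osteoblast fate, and Ibsp, bone sialoprotein, had 0 reads in all 8 libraries. A value of 0 need not mean that a gene is silent, because the table also gives 0 throughout for Hmgcs1, a cholesterol synthesis gene that cells use widely. Runx2, the regulator upstream of Sp7, stood at 284 ± 56.3 normalized counts (SD, n = 2) at day 0 and 238 ± 38.4 at day 7 (log2 -0.25 ± 0.20, adjusted p = 0.299). Alpl, the alkaline phosphatase that frees phosphate for mineral, fell 1.95-fold (log2 fold change -0.96 ± 0.28, adjusted p = 0.0120). Osteopontin, Spp1, rose 2.18-fold (log2 fold change 1.13 ± 0.16, adjusted p = 6.00e-05). Mgp, an inhibitor of calcification, rose 13.4-fold from 10839.5 ± 337 to 145520.0 ± 3054 (log2 fold change 3.75 ± 0.13, adjusted p = 3.96e-10). The pyrophosphate transporter Ank rose 1.77-fold (log2 0.82 ± 0.10), while the pyrophosphate-making enzyme Enpp1 fell 2.59-fold (log2 -1.37 ± 0.12). The osteocyte gene Dmp1 went from 2 to 23 reads over both libraries, a ratio of 10.5 (95% counting interval 2.59 to 91.6). Osteocalcin, Bglap, went from 1 to 5 reads, too few to test. Among osteoblast regulators 4 of 13 measured members were higher, 2 lower and 7 not called (in the same order of higher and lower, 4 and 2 adjusted over the list alone). Osteoblast regulators had a median log2 of -0.01 (adjusted p = 0.745, and adjusted p = 0.818 with an estimated correlation). Median and mean lay below 0 although the list test pointed up. For bone matrix and osteocyte markers 4 of 14 measured members were higher, 7 lower and 3 not called (4 and 7 adjusted over the list alone). Bone matrix markers had a median log2 of -0.20 (adjusted p = 0.452, and adjusted p = 0.576 with an estimated correlation). Regulators of phosphate, pyrophosphate and mineral had 5 higher, 4 lower and 7 not called (5 and 4 adjusted over the list alone). Mineral regulators had a median log2 of -0.04 (adjusted p = 0.618, and adjusted p = 0.818 with an estimated correlation). Their mean was 0.58, opposite in sign to the median. The fall of Alpl rested on single libraries, at -0.59 (adjusted p = 0.156) without the second of day 0 and -0.69 (adjusted p = 0.118) without the first of day 7. DESeq2 put its adjusted p at 0.0549.

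Proliferation genes fell in the same week. All 24 measured mitosis genes were lower (0 and 24 adjusted over the list alone), among them the proliferation antigen Mki67, 27.9-fold lower (log2 fold change -4.80 ± 0.20, adjusted p = 2.06e-09). The kinase Plk1 (log2 -4.69 ± 0.20) and cyclin B2, Ccnb2 (log2 -4.82 ± 0.28), fell alike. Mitosis genes had a median log2 of -3.72 (adjusted p = 1.39e-17, and adjusted p = 0.233 with an estimated correlation). DNA replication genes followed, 25 of 25 lower (0 and 25 adjusted over the list alone), with Mcm5 at log2 -3.16 ± 0.14 and Uhrf1 at -3.63 ± 0.24. Replication genes had a median log2 of -1.86 (adjusted p = 4.78e-13, and adjusted p = 0.235 with an estimated correlation). The contractile program of the myofibroblast fell as well: Acta2, smooth muscle actin, dropped 5.00-fold from 38250.4 ± 1706 to 7648 ± 46.1 (log2 fold change -2.32 ± 0.11, adjusted p = 4.40e-09). Tagln fell 8.71-fold and calponin, Cnn1, 18.1-fold. Of 20 myofibroblast and contractile genes, 14 were lower, 3 higher and 3 not called (3 and 14 adjusted over the list alone). Myofibroblast genes had a median log2 of -1.31 (adjusted p = 6.68e-05, and adjusted p = 0.289 with an estimated correlation). Col1a1, the chief fibroblast collagen, fell 3.65-fold (log2 fold change -1.87 ± 0.18, adjusted p = 2.57e-06) and Postn, a mark of activated fibroblasts, 2.57-fold (log2 -1.36 ± 0.13). Tcf21, a mark of resting cardiac fibroblasts, rose 3.56-fold (log2 fold change 1.83 ± 0.10, adjusted p = 1.36e-08) and Pdgfra 2.22-fold (log2 1.15 ± 0.13). Collagens and extracellular matrix genes as a group were split, 8 higher, 13 lower and 6 not called (9 and 13 adjusted over the list alone). Matrix genes had a median log2 of -0.24 (adjusted p = 0.142, and adjusted p = 0.793 with an estimated correlation). Resident fibroblast markers had 10 higher and 6 lower of 20 (10 and 6 adjusted over the list alone), with Dpep1 (log2 4.20 ± 0.10) and Gsn (log2 3.73 ± 0.17) leading. Resident markers had a median log2 of 0.34 (adjusted p = 0.112, and adjusted p = 0.576 with an estimated correlation).

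Glucocorticoid-responsive, complement and fat-cell genes rose early as well. Fkbp5, a co-chaperone induced by glucocorticoids, rose 10.3-fold from 531 ± 60.2 to 5449 ± 156 (log2 fold change 3.36 ± 0.10, adjusted p = 1.95e-10), and Zbtb16, a second such gene, rose from 5.51 ± 3.29 to 976 ± 70.9 (log2 fold change 7.32 ± 0.29, adjusted p = 1.29e-09). For glucocorticoid response genes 20 of 22 measured members were higher, 2 lower and 0 not called (20 and 2 adjusted over the list alone). Glucocorticoid genes had a median log2 of 2.43 (adjusted p = 4.20e-12, and adjusted p = 0.235 with an estimated correlation). The acute-phase gene Lcn2 rose 115-fold (log2 6.84 ± 0.21), and every one of 13 complement and antigen presentation genes was higher (13 and 0 adjusted over the list alone), including C3 (log2 4.57 ± 0.18) and C1s1 (log2 4.61 ± 0.16). Complement genes had a median log2 of 3.5 (adjusted p = 5.48e-11, and adjusted p = 0.289 with an estimated correlation). Fabp4, the fatty acid carrier of adipocytes, rose 21.6-fold (log2 4.43 ± 0.15) and Pparg, the regulator of fat-cell fate, 2.56-fold (log2 fold change 1.35 ± 0.26, adjusted p = 0.000763). Of 15 adipocyte markers 10 were higher, 1 lower and 4 not called (11 and 1 adjusted over the list alone). Adipocyte markers had a median log2 of 1.35 (adjusted p = 0.000353, and adjusted p = 0.289 with an estimated correlation). With members of 3 or fewer reads in a group set at the read floor, the median was 1.08. The cartilage collagen Col2a1 was 48.9-fold lower (log2 -5.61 ± 0.41). For chondrocyte markers 3 of 11 measured members were higher, 8 lower and 0 not called (3 and 8 adjusted over the list alone). Chondrocyte markers had a median log2 of -0.75 (adjusted p = 0.112, and adjusted p = 0.576 with an estimated correlation).

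Metabolic groups fell and immune cell genes rose by day 7. Cholesterol synthesis was lower in 21 of 22 genes (0 and 22 adjusted over the list alone), Fdps by log2 -1.65 ± 0.12. Cholesterol genes had a median log2 of -0.93 (adjusted p = 1.59e-08, and adjusted p = 0.351 with an estimated correlation). Glycolysis had 14 of 20 lower and 1 higher (2 and 14 adjusted over the list alone), led by the lactate exporter Slc16a3 (log2 -2.59 ± 0.16). Glycolysis genes had a median log2 of -0.69 (adjusted p = 0.000629, and adjusted p = 0.351 with an estimated correlation). Ribosomal protein genes, which share reads with many pseudogenes, were lower in 30 of 30 cases (0 and 30 adjusted over the list alone). Ribosomal genes had a median log2 of -0.92 (adjusted p = 5.48e-11, and adjusted p = 0.447 with an estimated correlation). Oxidative phosphorylation was lower in 13 of 28 (1 and 13 adjusted over the list alone). Oxidative phosphorylation had a median log2 of -0.26 (adjusted p = 0.00711, and adjusted p = 0.626 with an estimated correlation). Unfolded protein response genes were lower in 16 and higher in 5 of 24 (5 and 16 adjusted over the list alone), Chac1 among the former (log2 -1.84 ± 0.16). Unfolded protein genes had a median log2 of -0.65 (adjusted p = 0.000710, and adjusted p = 0.289 with an estimated correlation). Macrophage markers were higher in 19 of 20 (19 and 0 adjusted over the list alone), including Lyz2 12-fold (log2 3.59 ± 0.22) and Mrc1 (log2 4.02 ± 0.28). Macrophage markers had a median log2 of 2.74 (adjusted p = 1.14e-09, and adjusted p = 0.351 with an estimated correlation). Lysosome genes rose in 18 of 25 and fell in 1 (18 and 1 adjusted over the list alone), Hexa by log2 1.58 ± 0.10. Lysosome genes had a median log2 of 0.66 (adjusted p = 2.90e-05, and adjusted p = 0.289 with an estimated correlation). Interferon response genes gained in 18 of 26 (18 and 0 adjusted over the list alone), Oas2 by log2 3.35 ± 0.42. Interferon genes had a median log2 of 0.86 (adjusted p = 0.000252, and adjusted p = 0.576 with an estimated correlation). Immediate early genes rose in 14 of 22 against 4 lower (15 and 4 adjusted over the list alone), Fos by log2 3.13 ± 0.16. Immediate early genes had a median log2 of 1.03 (adjusted p = 0.00225, and adjusted p = 0.576 with an estimated correlation). In total 7492 genes were called, 3721 higher and 3771 lower, of which 1615 rose and 1224 fell at least 2-fold, and 15 of 31 testable lists were called. None of the 31 was called when the correlation between genes was estimated from these libraries.

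At day 14 Mgp, Spp1 and adipocyte genes were above day 0, and matrix genes were lower as a list. Mgp reached 223435 ± 1232 normalized counts, 20.6-fold above day 0 (log2 fold change 4.37 ± 0.13, adjusted p = 7.47e-11), and Spp1 4.04-fold (log2 fold change 2.01 ± 0.16, adjusted p = 2.16e-07). Runx2 fell 1.5-fold (log2 fold change -0.58 ± 0.20, adjusted p = 0.0189), Enpp1 3.91-fold (log2 -1.97 ± 0.12), and Alpl was not separable from its day 0 level (206 ± 11.7 against 167 ± 59.5, adjusted p = 0.291). Omd, osteomodulin of the bone matrix, rose 20.1-fold (log2 4.33 ± 0.20), Tnfsf11, the osteoclast-inducing ligand RANKL, 5.61-fold (log2 2.49 ± 0.27), and Dmp1 stood at 21 reads, a ratio of 10.9 (95% counting interval 2.66 to 95.6). Osteoblast regulators had 5 higher, 7 lower and 1 not called (5 and 7 adjusted over the list alone). For osteoblast regulators the median log2 was -0.36 (adjusted p = 0.755, and adjusted p = 0.886 with an estimated correlation). For bone matrix and osteocyte markers 4 of 14 measured members were higher, 5 lower and 5 not called (4 and 5 adjusted over the list alone). For bone matrix markers the median log2 was -0.02 (adjusted p = 0.943, and adjusted p = 0.974 with an estimated correlation). For phosphate, pyrophosphate and mineral regulators 5 of 16 measured members were higher, 7 lower and 4 not called (5 and 7 adjusted over the list alone). For mineral regulators the median log2 was -0.14 (adjusted p = 0.943, and adjusted p = 0.974 with an estimated correlation). Both lists had a median and test direction below 0 but a mean above it (0.27 and 0.56). The Runx2 call was lost without the first day 0 library (log2 -0.38, adjusted p = 0.186), without the second day 14 library (log2 -0.37, adjusted p = 0.134) and after removal of a transcript length and GC trend (log2 -0.07, adjusted p = 0.717).

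Matrix genes fell, in libraries that also differed from day 0 by -0.39 log2 units per doubling of transcript length. Col1a1 was 11.2-fold lower than at day 0 (log2 fold change -3.49 ± 0.18, adjusted p = 5.72e-09), Fn1 12.4-fold (log2 -3.63 ± 0.21) and fibrillin 1, Fbn1, 10.1-fold (log2 -3.33 ± 0.14). Of 27 collagens and matrix genes 24 were lower, 0 higher and 3 not called (0 and 24 adjusted over the list alone). For matrix genes the median log2 was -1.20 (adjusted p = 1.07e-07, and adjusted p = 0.468 with an estimated correlation). Myofibroblast genes had 14 of 20 lower (2 and 14 adjusted over the list alone), Actn1 by log2 -3.06 ± 0.11. For myofibroblast genes the median log2 was -1.62 (adjusted p = 0.000263, and adjusted p = 0.418 with an estimated correlation). Mitosis genes stayed down, 24 of 24 (0 and 24 adjusted over the list alone), Mki67 by log2 -5.75 ± 0.20. For mitosis genes the median log2 was -4.21 (adjusted p = 5.52e-13, and adjusted p = 0.288 with an estimated correlation). Replication genes were lower in 24 of 25 (0 and 25 adjusted over the list alone). For replication genes the median log2 was -1.98 (adjusted p = 6.14e-09, and adjusted p = 0.288 with an estimated correlation). Fabp4 reached 6319, log2 6.05 ± 0.15 above day 0, and the adipokine gene Adipoq, with 0 reads at day 0, was at least 13.8-fold higher. Adipocyte markers had 12 of 15 higher (12 and 1 adjusted over the list alone). For adipocyte markers the median log2 was 2.95 (adjusted p = 0.000110, and adjusted p = 0.288 with an estimated correlation). With genes at the read floor the median was 2.86. Fkbp5 held at 8.33-fold (log2 3.06 ± 0.10), and 20 of 22 glucocorticoid genes were higher (20 and 2 adjusted over the list alone). For glucocorticoid genes the median log2 was 2.74 (adjusted p = 6.14e-09, and adjusted p = 0.288 with an estimated correlation). Tcf21 rose further to 5.72-fold (log2 2.52 ± 0.10). Pdgfra, a growth factor receptor of fibroblasts, was back near day 0 (log2 0.10 ± 0.13, adjusted p = 0.525), a result that became a rise of 0.62 once the length and GC trend was removed.

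Macrophage genes stood far above day 0 at day 14. Lyz2, which shares reads with Lyz1, stood at 24332 ± 10405 against 681 ± 48.0 at day 0 (log2 5.09 ± 0.22), Tyrobp rose by log2 5.36 ± 0.26, and all 20 macrophage markers were higher (20 and 0 adjusted over the list alone). For macrophage markers the median log2 was 3.41 (adjusted p = 9.95e-09, and adjusted p = 0.418 with an estimated correlation). With genes at the read floor the median was 3.45. Endothelial markers moved opposite, 9 of 14 lower and 2 higher (2 and 9 adjusted over the list alone), led by VE-cadherin, Cdh5, 13.5-fold lower (log2 fold change -3.76 ± 0.34, adjusted p = 9.21e-07). For endothelial markers the median log2 was -1.52 (adjusted p = 0.163, and adjusted p = 0.598 with an estimated correlation). Complement genes were higher in 12 of 13 (12 and 0 adjusted over the list alone). For complement genes the median log2 was 3.15 (adjusted p = 1.07e-07, and adjusted p = 0.418 with an estimated correlation). Interferon genes rose in 22 of 26 (22 and 1 adjusted over the list alone), Oas2 by log2 4.71 ± 0.42 and Mx2 by 3.40 ± 0.44. For interferon genes the median log2 was 1.34 (adjusted p = 5.54e-05, and adjusted p = 0.608 with an estimated correlation). Cholesterol synthesis was lower in 21 of 22 (0 and 21 adjusted over the list alone). For cholesterol genes the median log2 was -1.40 (adjusted p = 3.42e-07, and adjusted p = 0.418 with an estimated correlation). Glycolysis fell in 16 of 20 (1 and 16 adjusted over the list alone). For glycolysis genes the median log2 was -1.15 (adjusted p = 3.01e-05, and adjusted p = 0.418 with an estimated correlation). Of 22 immediate early genes 14 were higher (14 and 4 adjusted over the list alone). For immediate early genes the median log2 was 0.95 (adjusted p = 0.0112, and adjusted p = 0.612 with an estimated correlation). Of 25 lysosome genes 17 were higher (17 and 4 adjusted over the list alone). For lysosome genes the median log2 was 0.72 (adjusted p = 0.00334, and adjusted p = 0.418 with an estimated correlation). Ribosomal protein genes, down at day 7, were no longer separable from day 0 as a list (4 higher, 4 lower, 22 not called, 0 and 2 adjusted over the list alone). For ribosomal genes the median log2 was 0.09 (adjusted p = 0.934, and adjusted p = 0.974 with an estimated correlation). These transcripts are short (median 922 nucleotides), and the day 14 libraries differed from day 0 by -0.39 log2 units per doubling of transcript length. That slope raises short transcripts, so this median need not mean a return to the day 0 level. Day 14 gave the most calls of the series, 9569 genes, 4757 higher and 4812 lower, with 2365 rising and 2168 falling at least 2-fold, and 13 lists.

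By day 21 Alpl stood above its starting level, with Runx2 not called. Alpl rose to 491 ± 197 from 167 ± 59.5, 2.90-fold (log2 fold change 1.53 ± 0.28, adjusted p = 0.000511), and the parathyroid hormone receptor Pth1r, carried by osteoblasts, rose 5.42-fold (log2 2.44 ± 0.16). Tnfsf11 was 9.28-fold higher (log2 3.21 ± 0.27), Omd 14.7-fold (log2 3.87 ± 0.20), Bmp2 2.67-fold (log2 1.42 ± 0.35) and Spp1 2.73-fold (log2 1.45 ± 0.16). Runx2 was not called (228 ± 44.0, adjusted p = 0.184), Bglap reached 10 reads over both libraries and Dmp1 17, a ratio of 8.74 (95% counting interval 2.08 to 78.0). Mgp remained 13.7-fold above day 0 (log2 3.78 ± 0.13) and Enpp1 2.94-fold below it (log2 -1.56 ± 0.12). Osteoblast regulators had 6 higher, 4 lower and 3 not called (7 and 4 adjusted over the list alone). Osteoblast regulators had a median log2 of 0.32 (adjusted p = 0.593, and adjusted p = 0.761 with an estimated correlation). For bone matrix and osteocyte markers 6 of 14 measured members were higher, 6 lower and 2 not called (6 and 6 adjusted over the list alone). Bone matrix markers had a median log2 of 0.14 (adjusted p = 0.942, and adjusted p = 0.942 with an estimated correlation). Among phosphate, pyrophosphate and mineral regulators 7 of 16 measured members were higher, 6 lower and 3 not called (7 and 6 adjusted over the list alone). Mineral regulators had a median log2 of 0.19 (adjusted p = 0.453, and adjusted p = 0.761 with an estimated correlation). Osteoclast markers were higher in 6 of 8 and lower in 1 (6 and 1 adjusted over the list alone), with the proton pump subunit Atp6v0d2 at a ratio of 68.4 (95% counting interval 18.6 to 571) and Acp5 at log2 2.19 ± 0.35. Osteoclast markers had a median log2 of 1.65 (adjusted p = 0.0373, and adjusted p = 0.297 with an estimated correlation). That call was lost under the stricter filter (median 1.12, adjusted p = 0.0797), without the expression filter (median 0.90, adjusted p = 0.0888) and without the second day 21 library (adjusted p = 0.0546). Macrophages also express genes of this list such as Acp5, and macrophage markers rose by more in this comparison, by a median of 3.37 with 19 of 20 higher.

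Myofibroblast and matrix genes were below day 0 at day 21, and cartilage genes were mixed. Col2a1 was 113-fold lower (log2 -6.82 ± 0.41), Sox9, the cartilage regulator, 2.00-fold (log2 -1.0 ± 0.11), though Comp, an extracellular protein of cartilage and tendon, rose 6.79-fold (log2 2.76 ± 0.18). Chondrocyte markers had 8 of 11 lower and 2 higher (2 and 8 adjusted over the list alone). Chondrocyte markers had a median log2 of -1.36 (adjusted p = 0.0346, and adjusted p = 0.491 with an estimated correlation). Acta2 was 4.68-fold lower (log2 -2.23 ± 0.11), and 16 of 20 myofibroblast genes were lower (3 and 16 adjusted over the list alone). Myofibroblast genes had a median log2 of -1.51 (adjusted p = 1.22e-05, and adjusted p = 0.249 with an estimated correlation). Collagens were lower in 15 of 27 and higher in 5 (7 and 16 adjusted over the list alone), Col1a1 by 4.70-fold (log2 -2.23 ± 0.18) and Loxl2 by 5.45-fold (log2 -2.45 ± 0.11). Matrix genes had a median log2 of -0.66 (adjusted p = 0.00607, and adjusted p = 0.622 with an estimated correlation). The scavenger receptor Scara5, which is not in the resident fibroblast list, rose by log2 7.04 ± 0.22. Resident fibroblast markers were higher in 11 and lower in 6 of 20 (11 and 6 adjusted over the list alone), Dpt by log2 3.53 ± 0.10. Resident markers had a median log2 of 0.49 (adjusted p = 0.0393, and adjusted p = 0.516 with an estimated correlation). Adipocyte markers rose in 13 of 15 (13 and 0 adjusted over the list alone), Plin4 by log2 4.60 ± 0.17. Adipocyte markers had a median log2 of 2.62 (adjusted p = 3.70e-06, and adjusted p = 0.159 with an estimated correlation). With genes at the read floor the median was 2.54. All 24 mitosis genes stayed lower (0 and 24 adjusted over the list alone). Mitosis genes had a median log2 of -4.22 (adjusted p = 6.62e-17, and adjusted p = 0.159 with an estimated correlation). So did 25 of 25 DNA replication genes (0 and 25 adjusted over the list alone). Replication genes had a median log2 of -1.94 (adjusted p = 1.64e-12, and adjusted p = 0.159 with an estimated correlation). Without the filter the chondrocyte median shrank to -0.25 (adjusted p = 0.174). Its call was also lost, at medians of -1.47 to -1.16, under the stricter filter (adjusted p = 0.0972), equal totals (0.0625), trend removal (0.0995) and omission of either day 0 library (0.06 and 0.0597). Trend removal took the collagen median to -0.43 (adjusted p = 0.096).

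Immediate early and inflammatory genes stood far above day 0 at day 21. Fosb, an AP-1 subunit induced within minutes of a stimulus, rose 124-fold to 4814 ± 1188 (log2 fold change 6.95 ± 0.26, adjusted p = 4.30e-10), with Nr4a1 at log2 5.49 ± 0.21, and 19 of 22 immediate early genes were higher (19 and 1 adjusted over the list alone). Immediate early genes had a median log2 of 3.06 (adjusted p = 2.26e-09, and adjusted p = 0.297 with an estimated correlation). The neutrophil attractant Cxcl1 rose by log2 6.63 ± 0.32, and chemokines and inflammatory cytokines were higher in 14 of 18 and lower in 1 (14 and 1 adjusted over the list alone), though Il6 was not called (adjusted p = 0.370). Chemokines and cytokines had a median log2 of 1.40 (adjusted p = 0.000212, and adjusted p = 0.162 with an estimated correlation). Glucocorticoid genes were higher in 20 of 22 (20 and 1 adjusted over the list alone). Glucocorticoid genes had a median log2 of 3.21 (adjusted p = 2.30e-13, and adjusted p = 0.159 with an estimated correlation). Complement genes were higher in 13 of 13 (13 and 0 adjusted over the list alone). Complement genes had a median log2 of 3.64 (adjusted p = 3.83e-10, and adjusted p = 0.297 with an estimated correlation). Interferon genes were higher in 21 of 26 (21 and 0 adjusted over the list alone). Interferon genes had a median log2 of 1.18 (adjusted p = 1.97e-05, and adjusted p = 0.516 with an estimated correlation). Macrophage markers rose in 19 of 20 (19 and 0 adjusted over the list alone), Ctss by log2 4.77 ± 0.21. Macrophage markers had a median log2 of 3.37 (adjusted p = 7.58e-10, and adjusted p = 0.306 with an estimated correlation). Endothelial markers fell in 9 of 14 and rose in 1 (1 and 9 adjusted over the list alone), Cdh5 29.8-fold lower (log2 -4.90 ± 0.34) and Tie1 by log2 -3.06 ± 0.32. Endothelial markers had a median log2 of -1.87 (adjusted p = 0.0393, and adjusted p = 0.411 with an estimated correlation). That endothelial call was lost under the stricter filter, where the median shrank to -0.57 (adjusted p = 0.478), so its size rests on members with low counts. Under equal totals (-1.97, adjusted p = 0.063) and trend removal (-2.00, adjusted p = 0.14) the median held but the call did not. It was lost as well without the second day 0 (0.104), second day 14 (0.0503) or first day 21 (0.0806) library. Lysosome genes were higher in 23 of 25 (23 and 0 adjusted over the list alone), Ctsb by log2 1.89 ± 0.11. Lysosome genes had a median log2 of 0.95 (adjusted p = 5.53e-08, and adjusted p = 0.162 with an estimated correlation).

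Cholesterol synthesis and glycolysis were still below day 0 at 21 days. Cholesterol synthesis was lower in 16 of 22 genes (0 and 16 adjusted over the list alone). Cholesterol genes had a median log2 of -0.62 (adjusted p = 5.44e-05, and adjusted p = 0.458 with an estimated correlation). Glycolysis was lower in 15 of 20 (1 and 15 adjusted over the list alone), Slc16a3 by log2 -4.29 ± 0.16. Glycolysis genes had a median log2 of -0.78 (adjusted p = 0.000130, and adjusted p = 0.297 with an estimated correlation). Ribosomal protein genes were lower in 23 of 30 (0 and 26 adjusted over the list alone). Ribosomal genes had a median log2 of -0.41 (adjusted p = 0.000130, and adjusted p = 0.622 with an estimated correlation). Oxidative phosphorylation genes were mostly not called (1 higher, 8 lower, 19 not called, 1 and 7 adjusted over the list alone). Oxidative phosphorylation had a median log2 of -0.06 (adjusted p = 0.460, and adjusted p = 0.864 with an estimated correlation). Unfolded protein response genes were mixed (6 higher, 10 lower, 8 not called, 6 and 11 adjusted over the list alone). Unfolded protein genes had a median log2 of -0.13 (adjusted p = 0.313, and adjusted p = 0.622 with an estimated correlation). In total 8031 genes were called, 4034 higher and 3997 lower, 1873 rising and 1365 falling at least 2-fold, and 19 lists. Scaling libraries to equal totals put the median of all genes at -0.107 in this comparison, about the size of the smallest list medians given here.

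**Figure D2:**
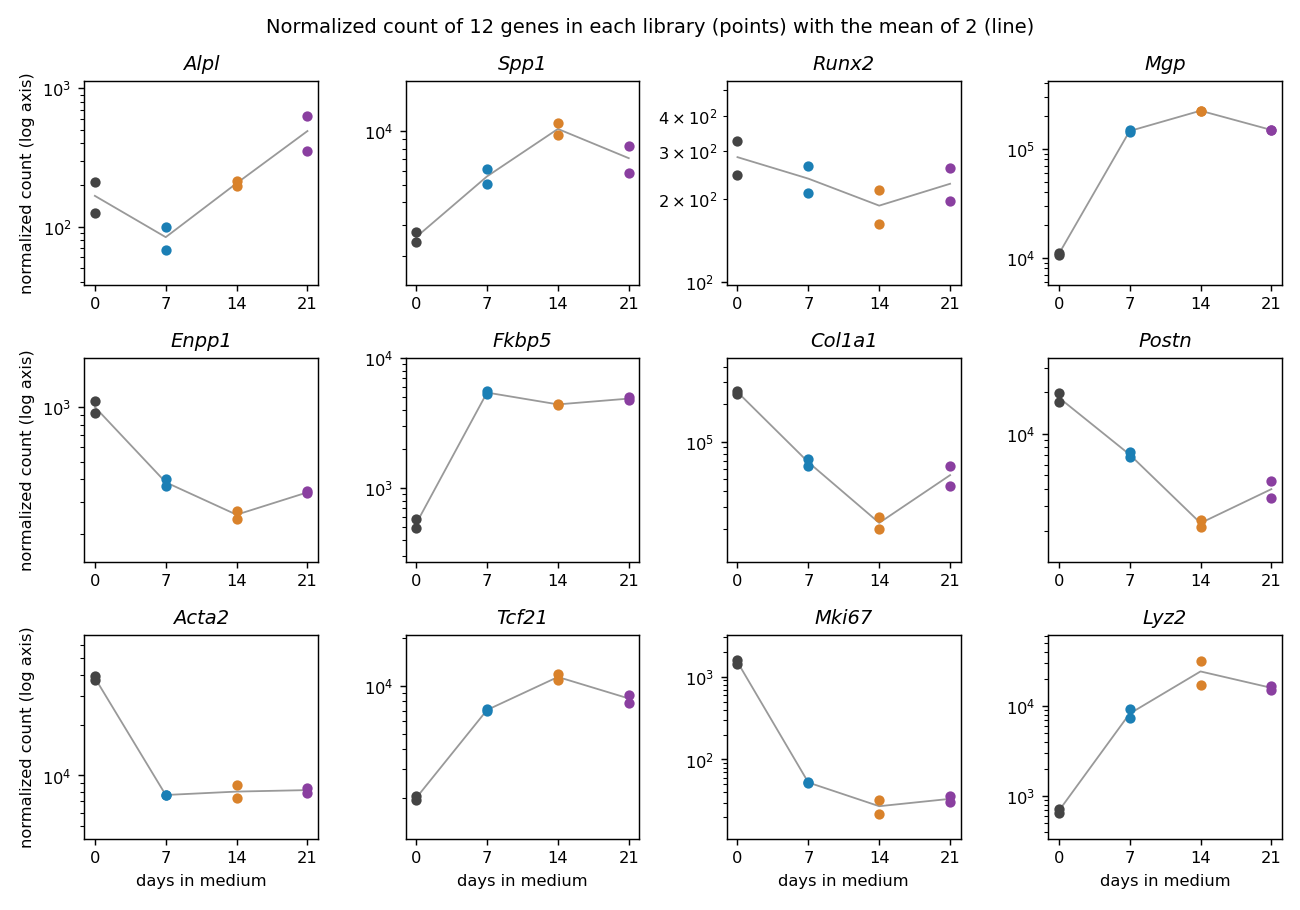
Normalized counts of 12 genes over days 0, 7, 14 and 21 on a logarithmic axis, with 1 point per library and lines through the means.

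From day 7 to day 14, Alpl rose, while matrix genes fell. Alpl rose 2.47-fold from 84.1 ± 22.3 to 206 ± 11.7 (log2 fold change 1.31 ± 0.28, adjusted p = 0.00236), Pth1r 2.38-fold (log2 1.25 ± 0.16) and Tnfsf11 3.28-fold (log2 1.71 ± 0.27), while Runx2 was not called (adjusted p = 0.183). Col1a1 fell 3.07-fold (log2 fold change -1.62 ± 0.18, adjusted p = 4.21e-05), Postn 3.12-fold (log2 -1.64 ± 0.13) and Fn1 4.58-fold (log2 -2.19 ± 0.21). Of the collagens and matrix genes 25 of 27 were lower and 0 higher (0 and 27 adjusted over the list alone). For matrix genes the median log2 was -1.04 (adjusted p = 3.67e-12, and adjusted p = 0.933 with an estimated correlation). Ribosomal protein genes rose in 30 of 30 cases (30 and 0 adjusted over the list alone), Rpl35 by log2 1.30 ± 0.15. For ribosomal genes the median log2 was 0.96 (adjusted p = 5.93e-14, and adjusted p = 0.933 with an estimated correlation). Oxidative phosphorylation genes were higher in 23 of 28 (24 and 1 adjusted over the list alone), Cox7a2 by log2 1.11 ± 0.13. For oxidative phosphorylation the median log2 was 0.45 (adjusted p = 4.01e-06, and adjusted p = 0.933 with an estimated correlation). Mmp9, a protease of macrophages and osteoclasts, rose by log2 4.55 ± 0.53 and the macrophage receptor Marco by 3.25 ± 0.71. Macrophage markers were higher in 10 of 20 (10 and 0 adjusted over the list alone). For macrophage markers the median log2 was 0.68 (adjusted p = 0.00229, and adjusted p = 0.933 with an estimated correlation). Interferon genes were higher in 12 of 26 against 1 lower (12 and 1 adjusted over the list alone). For interferon genes the median log2 was 0.52 (adjusted p = 0.0102, and adjusted p = 0.933 with an estimated correlation). Glycolysis fell in 12 of 20 (1 and 13 adjusted over the list alone), Eno1 by log2 -1.14 ± 0.14. For glycolysis genes the median log2 was -0.33 (adjusted p = 0.00207, and adjusted p = 0.933 with an estimated correlation). Cdh5 fell 5.53-fold (log2 -2.47 ± 0.34), and 10 of 14 endothelial markers were lower (1 and 11 adjusted over the list alone). For endothelial markers the median log2 was -0.90 (adjusted p = 0.0861, and adjusted p = 0.933 with an estimated correlation).

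This step also carried a library-wide trend with transcript length, at -0.38 log2 units per doubling of length, so that short transcripts gained and long ones lost in the day 14 libraries. With the length and GC trend removed, the calls of oxidative phosphorylation (median 0.01, adjusted p = 0.953), Spp1 (log2 0.26 in place of 0.89 ± 0.16, adjusted p = 0.084), Enpp1 and Fkbp5 were lost, and Mgp (0.62 ± 0.13) turned to -0.18 (adjusted p = 0.297). The ribosomal median dropped from 0.96 to 0.31 and the collagen median went from -1.04 to -0.70. The interferon call was lost without the second day 7 library (median 0.30, adjusted p = 0.129) or the first day 14 library (median 0.13, adjusted p = 0.62), and the macrophage call without the second day 14 library (median 0.29, adjusted p = 0.0726). Of 7038 genes called, 3385 were higher and 3653 lower, 728 rose and 687 fell at least 2-fold, and 6 lists were called.

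From day 14 to day 21, immediate early and matrix genes rose together. Fosb rose 19.1-fold (log2 fold change 4.26 ± 0.26, adjusted p = 3.41e-06), Nr4a1 by log2 3.35 ± 0.21, Jun by 2.99 ± 0.23 and Atf3 by 2.54 ± 0.20, and 19 of 22 immediate early genes were higher (19 and 0 adjusted over the list alone). Immediate early genes had a median log2 of 1.80 (adjusted p = 4.95e-15, and adjusted p = 0.592 with an estimated correlation). Col1a1 regained 2.39-fold (log2 fold change 1.25 ± 0.18, adjusted p = 0.000609), Fn1 3.24-fold (log2 1.69 ± 0.21) and Col6a3 3.27-fold (log2 1.71 ± 0.19). Of 27 collagens and matrix genes 23 were higher (24 and 0 adjusted over the list alone). Matrix genes had a median log2 of 0.80 (adjusted p = 2.09e-11, and adjusted p = 0.592 with an estimated correlation). Alpl rose 2.28-fold (log2 fold change 1.19 ± 0.28, adjusted p = 0.00783), a call lost without the first day 21 library (log2 0.77, adjusted p = 0.073). Chemokines were higher in 8 of 18 (9 and 0 adjusted over the list alone), Cxcl1 by log2 2.61 ± 0.32 and Il6 by 1.43 ± 0.17. Chemokines and cytokines had a median log2 of 0.59 (adjusted p = 0.000468, and adjusted p = 0.592 with an estimated correlation). Cholesterol genes rose in 16 of 22 (17 and 0 adjusted over the list alone). Cholesterol genes had a median log2 of 0.58 (adjusted p = 9.24e-07, and adjusted p = 0.592 with an estimated correlation). Lysosome genes were higher in 16 of 25 (16 and 1 adjusted over the list alone). Lysosome genes had a median log2 of 0.35 (adjusted p = 0.000468, and adjusted p = 0.592 with an estimated correlation). Unfolded protein response genes were higher in 11 and lower in 2 of 24 (12 and 2 adjusted over the list alone). Unfolded protein genes had a median log2 of 0.28 (adjusted p = 0.00215, and adjusted p = 0.592 with an estimated correlation). Proteases and inhibitors were higher in 11 and lower in 2 of 21 (11 and 2 adjusted over the list alone). Proteases and inhibitors had a median log2 of 0.31 (adjusted p = 0.00835, and adjusted p = 0.592 with an estimated correlation). Glycolysis was higher in 8 and lower in 0 of 20 (8 and 0 adjusted over the list alone). Glycolysis genes had a median log2 of 0.19 (adjusted p = 0.00484, and adjusted p = 0.592 with an estimated correlation). That call was lost without the first day 14 library (median 0.12, adjusted p = 0.0914), and the protease call under quantile scaling (median 0.12, adjusted p = 0.052).

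Signalling lists passed narrowly and ribosomal genes fell over the same week. TGF-beta and BMP response genes were higher in 12 and lower in 2 of 22 (12 and 2 adjusted over the list alone), Smad7 by log2 1.28 ± 0.13. TGF-beta and BMP genes had a median log2 of 0.45 (adjusted p = 0.0263, and adjusted p = 0.592 with an estimated correlation). Wnt targets and antagonists were higher in 5 of 16 (5 and 0 adjusted over the list alone), Sfrp2 by log2 2.34 ± 0.18. Wnt genes had a median log2 of 0.30 (adjusted p = 0.0484, and adjusted p = 0.592 with an estimated correlation). Ribosomal protein genes were lower in 21 of 30 (0 and 26 adjusted over the list alone). Ribosomal genes had a median log2 of -0.46 (adjusted p = 3.82e-09, and adjusted p = 0.649 with an estimated correlation). Oxidative phosphorylation genes fell in 14 of 28 (1 and 15 adjusted over the list alone). Oxidative phosphorylation had a median log2 of -0.27 (adjusted p = 8.88e-05, and adjusted p = 0.649 with an estimated correlation). Among noncoding RNAs Meg3 fell from 302 ± 29.0 to 32.5 (log2 -3.24 ± 0.27), Neat1, the scaffold of paraspeckles, by log2 -2.80 ± 0.23, and Malat1 by -2.35 ± 0.21. The Wnt and TGF-beta calls were lost under the stricter filter (adjusted p = 0.0701 and 0.0555) and without the second day 21 library (0.0525 and 0.0605), the Wnt call also without the second day 14 (0.0632) or first day 21 (0.0642) library. Further losses were the Wnt call at pseudocount 0.5 (adjusted p = 0.0509), without the filter (0.0588) and under trend removal (0.106), and the TGF-beta call under quantile scaling (0.0527). Trend removal took the ribosomal call (median -0.06, adjusted p = 0.0914) and turned the oxidative phosphorylation median to 0.01. Calls numbered 4664, 2735 higher and 1929 lower, with 352 rising and 202 falling at least 2-fold, and 12 lists, and the share called higher, 58.6%, was 40.3% with libraries scaled to equal totals. The count was 2302 without the second day 21 library, 2556 without the second day 14 library, 5735 without the first day 14 library and 2635 with only those times fitted.

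Between day 7 and day 21 fewer genes were called than in any other comparison, and Alpl was among the rises. Alpl rose 5.64-fold from 84.1 ± 22.3 to 491 ± 197 (log2 fold change 2.50 ± 0.28, adjusted p = 0.000238), Tnfsf11 5.43-fold (log2 2.44 ± 0.27), Pth1r 2.90-fold (log2 1.54 ± 0.16) and Comp 3.24-fold (log2 1.70 ± 0.18). Runx2 (adjusted p = 0.870), Mgp (adjusted p = 0.903), Spp1 (adjusted p = 0.219) and Fkbp5 (adjusted p = 0.355) were not called. Bone matrix and osteocyte markers were higher in 4, lower in 0 and not called in 10 of 14 (4 and 0 adjusted over the list alone). For bone matrix markers the median log2 was 0.35 (adjusted p = 0.0189, and adjusted p = 0.250 with an estimated correlation). That call was lost without the expression filter (adjusted p = 0.0959). Immediate early genes were higher in 19 of 22 (19 and 0 adjusted over the list alone), Fosb by 20.2-fold (log2 4.34 ± 0.26) and Egr2 by log2 2.99 ± 0.19. For immediate early genes the median log2 was 1.86 (adjusted p = 3.26e-26, and adjusted p = 0.178 with an estimated correlation). Chemokines were higher in 8 of 18 (10 and 0 adjusted over the list alone), Cxcl1 by log2 3.51 ± 0.32 and Il6 by 1.6 ± 0.17. For chemokines and cytokines the median log2 was 0.77 (adjusted p = 3.40e-08, and adjusted p = 0.178 with an estimated correlation). Unfolded protein response genes were higher in 13 of 24 (16 and 1 adjusted over the list alone), the chaperone Hspa5 by log2 0.81 ± 0.10. For unfolded protein genes the median log2 was 0.41 (adjusted p = 2.00e-08, and adjusted p = 0.178 with an estimated correlation). Endothelial markers fell in 6 of 14 (0 and 7 adjusted over the list alone), Cdh5 by log2 -3.61 ± 0.34 and Tie1 by -2.44 ± 0.32. For endothelial markers the median log2 was -0.87 (adjusted p = 4.48e-06, and adjusted p = 0.178 with an estimated correlation). Macrophage markers rose in 4 of 20 (9 and 0 adjusted over the list alone). For macrophage markers the median log2 was 0.67 (adjusted p = 3.02e-05, and adjusted p = 0.470 with an estimated correlation). With genes at the read floor the median was 0.76.

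Further groups also shifted over these 2 weeks. Ribosomal protein genes were higher in 21 of 30 (30 and 0 adjusted over the list alone). For ribosomal genes the median log2 was 0.50 (adjusted p = 1.85e-15, and adjusted p = 0.356 with an estimated correlation). Oxidative phosphorylation was higher in 3 of 28 (3 and 0 adjusted over the list alone). For oxidative phosphorylation the median log2 was 0.22 (adjusted p = 8.70e-05, and adjusted p = 0.497 with an estimated correlation). Lysosome genes gained in 9 of 25 (11 and 0 adjusted over the list alone). For lysosome genes the median log2 was 0.22 (adjusted p = 2.68e-06, and adjusted p = 0.243 with an estimated correlation). Resident fibroblast markers were higher in 8 and lower in 1 of 20 (8 and 1 adjusted over the list alone). For resident markers the median log2 was 0.26 (adjusted p = 0.000523, and adjusted p = 0.342 with an estimated correlation). Collagens were lower in 9 of 27 (1 and 11 adjusted over the list alone). For matrix genes the median log2 was -0.33 (adjusted p = 9.40e-06, and adjusted p = 0.479 with an estimated correlation). Higher too were 4 of 15 adipocyte markers (5 and 0 adjusted over the list alone), 8 of 22 glucocorticoid genes (11 and 0 adjusted over the list alone) and 5 of 22 cholesterol genes (7 and 0 adjusted over the list alone). For adipocyte markers the median log2 was 0.37 (adjusted p = 0.00126, and adjusted p = 0.250 with an estimated correlation). For glucocorticoid genes the median log2 was 0.33 (adjusted p = 3.38e-05, and adjusted p = 0.293 with an estimated correlation). For cholesterol genes the median log2 was 0.30 (adjusted p = 9.49e-06, and adjusted p = 0.381 with an estimated correlation). TGF-beta and BMP genes were higher in 8 and lower in 1 of 22 (12 and 2 adjusted over the list alone). For TGF-beta and BMP genes the median log2 was 0.44 (adjusted p = 0.000394, and adjusted p = 0.293 with an estimated correlation). Mitosis genes were lower in 3 of 24 (0 and 6 adjusted over the list alone). For mitosis genes the median log2 was -0.33 (adjusted p = 8.70e-05, and adjusted p = 0.293 with an estimated correlation). Lists with few called members still passed, among them interferon (1 of 26 higher, 0 and 0 adjusted over the list alone), glycolysis (1 higher and 2 lower of 20, 2 and 4 adjusted over the list alone) and p53 targets (4 of 19 higher, 6 and 1 adjusted over the list alone). For interferon genes the median log2 was 0.37 (adjusted p = 0.00404, and adjusted p = 0.571 with an estimated correlation). For glycolysis genes the median log2 was -0.13 (adjusted p = 0.0324, and adjusted p = 0.479 with an estimated correlation). For p53 targets the median log2 was 0.14 (adjusted p = 0.0330, and adjusted p = 0.417 with an estimated correlation). Those 3 calls were lost, the interferon median going to 0.11 and 0.16, without the second day 7 library (adjusted p = 0.22, 0.206 and 0.0778) or the second day 21 library (0.263, 0.114 and 0.176), and oxidative phosphorylation with the length and GC trend removed (median 0.00, adjusted p = 0.87). Calls numbered 1182, 738 higher and 444 lower, 211 rising and 72 falling at least 2-fold, with 19 lists. This count ran from 262 without the first day 7 library to 2188 without the first day 14 library, and was 2181 without both day 14 libraries. The share called higher, 62.4%, was 39.4% under equal totals and 51.5% under quantile scaling.

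**Figure D3:**
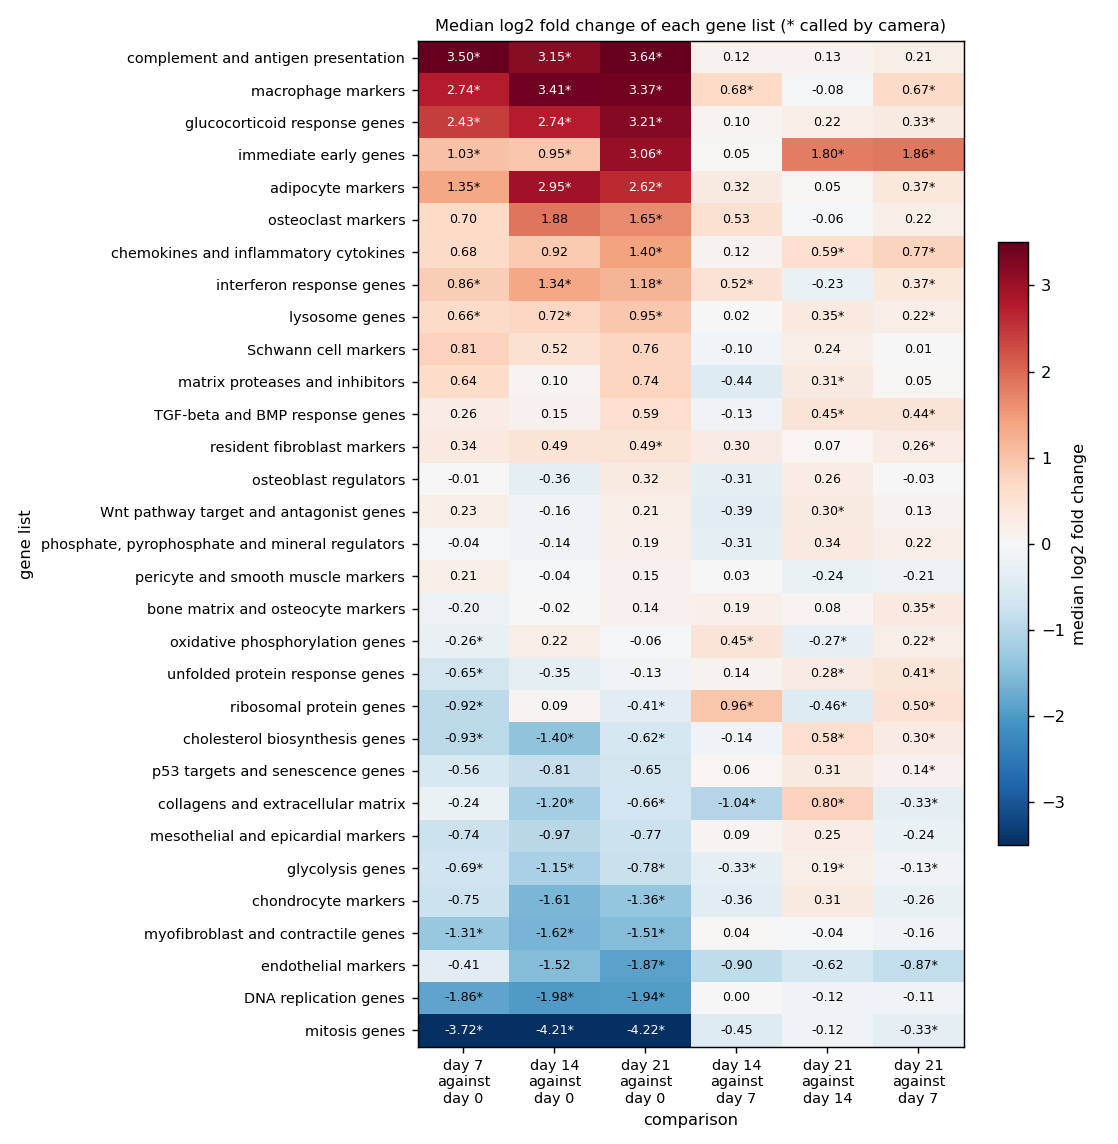
Median log2 fold change of each gene list in the 6 comparisons of times, with lists called at the preset correlation starred.

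Changes of the first and the last week were almost uncorrelated, with somewhat more reversals than independent calls would give. Across the tested genes, the log2 differences of day 7 minus day 0 and of day 21 minus day 14, which share no library, correlated at r = -0.06 (rho = -0.08). Called in both weeks were 683 genes higher then higher and 459 lower then lower, against 752 and 538 for independent calls. Reversals numbered 571 genes higher then lower and 939 lower then higher, against 531 and 762. These counts depend on scaling, since the share called higher at day 21 against day 14 was 58.6% and under equal totals 40.3%. Fos and Fosb belong to the genes that rose in both weeks, and Col1a1 and Postn to those that fell and then recovered in part. Mgp and Spp1 rose and then fell, but the later falls were lost once the length and GC trend was removed (log2 -0.11 and -0.21).

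Most of the first-week changes were still present at 21 days. Both comparisons with day 0 called 6409 genes in the same direction, 3252 higher and 3157 lower, which is 85.5% of the day 7 calls, against 1110 and 1114 for independent calls. Opposite calls numbered 4 and 8 genes. Tcf21, Fkbp5, Mgp and Fabp4 were among the shared rises, and Col1a1, Acta2, Enpp1 and Mki67 among the shared falls. Alpl, lower at day 7 and higher at day 21, was 1 of the few to turn. Its day 7 call was lost in some single-library omissions and with DESeq2, so that turn is not firm. Because both comparisons use the same day 0 libraries, shared noise could add to the overlap. In 100 simulated series with no true change the shared calls averaged 0.1 and never exceeded 2. With no true change few calls arise at all, so this does not measure what shared noise adds where many genes change. The covariance between the differences was 1.30, where the shared libraries account for 0.0246. The correlation was 0.94, where shared libraries with no true change would give 0.50. The controls were not divided between the comparisons, since that would leave 1 library to each. A further 1071 genes were called at day 7 only and 1610 at day 21 only.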

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

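Chosen only after the result was seen were the 3 tests on immediate early genes and the test of fibroblast loss, whereas the collagen, ribosomal, nuclear RNA and further macrophage tests were written before their results.

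Day 14 stood apart from the times on either side of it. Collagens and matrix genes went from a median of -1.04 against day 7 to 0.80 for day 21 against day 14, and ribosomal protein genes from 0.96 to -0.46, with a length slope of -0.38 and then 0.25 over all genes. A length- and GC-dependent difference between harvests could produce both. After removal of the fitted trend the collagen median at day 14 against day 7 was still -0.70 (-0.79 to -0.56 over pairs of libraries). The trend as fitted therefore did not take up the whole collagen fall. The median collagen transcript is 5564 nucleotides long against 3095 for all genes. Lengths were those of the longest annotated transcript per gene, so an imperfect fit could leave part of the fall, which was not tested. For ribosomal protein genes 0.31 was left (0.28 to 0.37), and because they are among the shortest transcripts (median 922 nucleotides) the trend could in part rest on them, which was not tested, so that test does not decide. Of 22 nuclear noncoding RNAs written down, 12 could be tested. At day 14, 10 of the 12 lay above the mean of days 7 and 21, 2900097C17Rik by only 0.05. The median difference was 0.59 in the lower day 14 library and 0.87 in the higher, which is compatible with more nuclear RNA in those extracts. Whether that bears on the collagen fall was not tested.

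Immediate early genes surged at day 21. A low day 14 reference might have inflated the median of 1.80 for day 21 against day 14, but the rise against day 7 was 1.86 (1.52 to 2.19 over pairs of libraries), which speaks against that. A steady climb would have shown by day 14, where the median against day 7 was 0.046 (-0.18 to 0.39). Handling of the cells at that harvest was tested by how far the day 21 libraries differ from each other, a median of 0.35 where 1 had been set as the sign of handling, while 17 of 22 genes had both day 21 libraries above all 6 others. That test does not decide, since handling shared by both day 21 libraries is confounded with time in the medium.

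Macrophage genes rose as endothelial genes fell. Were fibroblasts lost and all other cells left alike, both groups would rise, yet at day 21 against day 0 the endothelial median differed from the macrophage median by -5.24 (-5.42 to -4.91 over pairs of libraries, from medians of -1.87 and 3.37). A larger macrophage share should lift further macrophage genes, and 25 such genes outside the list had a median of 2.80 (2.59 to 3.30), 24 of them called higher and 0 lower, which is consistent with it. Induction of these genes within fibroblasts was not tested, and bulk libraries do not separate cells. The size of the endothelial fall rests on genes with low counts, as under the stricter filter its median was -0.57 (adjusted p = 0.478).

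Results in which the effect against day 0 differed between times follow, first day 14 against day 7 with its 7038 called genes. List medians there were collagens and matrix -1.04, interferon 0.52, glycolysis -0.33, oxidative phosphorylation 0.45, macrophage 0.68 and ribosomal protein genes 0.96. Among named genes Alpl changed by 1.31, Spp1 by 0.89, Enpp1 by -0.59, Ank by -0.52, Mgp by 0.62, Col1a1 by -1.62, Postn by -1.64, Pdgfra by -1.05, Tcf21 by 0.69, Fkbp5 by -0.30 and Sox9 by -0.95.

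Day 21 against day 14 had 4664 called genes. Medians were collagens and matrix 0.80, proteases 0.31, chemokines 0.59, cholesterol synthesis 0.58, glycolysis 0.19, oxidative phosphorylation -0.27, unfolded protein response 0.28, Wnt 0.30, TGF-beta and BMP 0.45, immediate early genes 1.80, lysosome 0.35 and ribosomal protein genes -0.46. Alpl changed by 1.19, Spp1 by -0.56, Enpp1 by 0.41, Ank by 0.46, Mgp by -0.59, Col1a1 by 1.25, Postn by 0.80, Pdgfra by 1.11, Tcf21 by -0.45 and Sox9 by 0.31. With the length and GC trend removed the calls of Enpp1 (0.06, adjusted p = 0.695), Tcf21 (-0.23, adjusted p = 0.0892), Sox9 (0.13, adjusted p = 0.264), Spp1 (-0.21, adjusted p = 0.195) and Mgp (-0.11, adjusted p = 0.561) were lost. Enpp1 was also not called under equal totals (0.30), with only those times fitted (adjusted p = 0.0874) or without the second day 14 (adjusted p = 0.0898), first day 21 (0.0596) or second day 21 (0.0645) library. Spp1 was lost without the second day 14 (-0.46, adjusted p = 0.0859) or second day 21 library (-0.31, adjusted p = 0.157). Sox9 was lost under most other settings, from pseudocount 0.5 (adjusted p = 0.0507) to equal totals (0.20, adjusted p = 0.169), and was 0.15 without the second day 21 library (adjusted p = 0.346).

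Day 21 against day 7 had 1182 called genes. Medians were bone matrix 0.35, adipocyte 0.37, resident fibroblast 0.26, collagens and matrix -0.33, mitosis -0.33, interferon 0.37, chemokines 0.77, glucocorticoid 0.33, cholesterol synthesis 0.30, glycolysis -0.13, oxidative phosphorylation 0.22, unfolded protein response 0.41, TGF-beta and BMP 0.44, macrophage 0.67, endothelial -0.87, immediate early genes 1.86, p53 targets 0.14, lysosome 0.22 and ribosomal protein genes 0.50. Alpl changed by 2.50, Postn by -0.84 and Sox9 by -0.63.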

How the results depend on the processing

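Chosen only after the data were seen were the removal of the length and GC trend and the fits without the day 14 or without the day 21 libraries. Every other alternative was planned. Outside single-library omissions, 160 summary values stayed as they were and 9 moved. Among list results 1905 stayed, 26 became stronger, 107 weaker and 2 reversed, and among named genes 4115, 5, 32 and 1.

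A pair of counts depended on the choices. For day 21 against day 7 the 1182 calls became 739 without the expression filter and 2181 without the day 14 libraries, and ran from 262 to 2188 over single-library omissions (262 and 298 without a day 7 library, 520 without the first day 21 library, 759 without either day 0 library, 2188 and 2175 without a day 14 library). For day 21 against day 14 the 4664 calls became 2635 when only those times were fitted, and ran from 2302 without the second day 21 library to 5735 without the first day 14 library, with 2556 without the second day 14 library. Noisier day 14 and day 21 libraries enter the common variance, but the cause was not tested.

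Removal of the length and GC trend reversed 3 results. Oxidative phosphorylation at day 14 against day 7 went from 0.45 to 0.0128 in median with the list test pointing down (adjusted p = 0.953), at day 21 against day 14 from -0.27 to 0.0127 (adjusted p = 0.768), and Mgp at day 14 against day 7 from 0.62 to -0.18 (adjusted p = 0.297). Called genes numbered 8256, 9585, 8810, 5374, 3502 and 1221 in the order day 7, 14 and 21 against day 0, day 14 against 7, day 21 against 14 and day 21 against 7. Of the 7038 calls at day 14 against day 7, 3695 kept call and direction and 96 were called the other way, and of the 9569 at day 14 against day 0, 7578 and 178. Of the 4664 at day 21 against day 14, 2477 kept call and direction and 0 were called the other way.

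With the correlation between genes estimated from the libraries, the numbers of called lists, 15, 13, 19, 6, 12 and 19, all became 0. That alternative estimates a correlation from 4 residual degrees of freedom and also takes list p-values from a distribution with those 4. The loss therefore cannot be laid to correlation between genes alone. Bone matrix markers at day 21 against day 7 had an estimated correlation of -0.02, below the preset 0.01. Their adjusted p from camera still went from 0.0189 to 0.250, a value that also depends on the other lists. How much each difference contributes was not tested.

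Libraries carry replicate numbers, and a fit with replicate number as a block called 7443, 9522, 7973, 6960, 4521 and 949 genes and 15, 13, 18, 6, 11 and 19 lists. Blocking ended the resident fibroblast call at day 21 against day 0 (adjusted p = 0.052) and the Wnt call at day 21 against day 14 (adjusted p = 0.0594), but the replicate differences of different times correlated at only -0.04 to 0.07, so the numbers do not mark a pairing.

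In single-library omissions 103 summary values stayed and 9 moved, lists counted 1433 unchanged, 35 stronger and 20 weaker, and named genes 2474, 4 and 48. Calls lost in this way include Alpl and Sox9 at day 7 against day 0, Runx2 and Ank at day 14 against day 0, Fkbp5, Mx2 and Oas2 at day 14 against day 7, Alpl, Spp1, Enpp1 and Sox9 at day 21 against day 14, and Postn, Sox9 and Omd at day 21 against day 7. The cause was not tested.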

Other observations

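Against day 0, several groups had changed members at day 21 without passing the list test. Wnt pathway genes split: Dkk3 (log2 5.22 ± 0.16), the antagonist Sfrp2 (log2 3.90 ± 0.18) and the feedback target Axin2 (log2 2.87 ± 0.40) rose against day 0, while Wisp1 fell (log2 -4.97 ± 0.15). Of 16 such genes 7 were higher and 6 lower (8 and 6 adjusted over the list alone). Wnt genes had a median log2 of 0.21 (adjusted p = 0.693, and adjusted p = 0.781 with an estimated correlation). In the TGF-beta and BMP group the BMP antagonist Chrdl1 rose by log2 5.2 ± 0.31 and Id4 by 3.69 ± 0.28. Of 22 such genes 10 were higher and 6 lower (10 and 6 adjusted over the list alone). TGF-beta and BMP genes had a median log2 of 0.59 (adjusted p = 0.0905, and adjusted p = 0.516 with an estimated correlation). Matrix proteases and inhibitors gained Mmp9 (log2 5.27 ± 0.53) and Mmp3 (log2 3.78 ± 0.17), and Timp4, with 0 reads at day 0, was at least 26.1-fold higher. Of 21 such genes 13 were higher and 7 lower (13 and 8 adjusted over the list alone). Proteases and inhibitors had a median log2 of 0.74 (adjusted p = 0.10, and adjusted p = 0.574 with an estimated correlation). Among p53 targets and senescence genes Igfbp3, a binder of insulin-like growth factors, rose by log2 5.68 ± 0.22, but 11 of 19 were lower and 6 higher (6 and 11 adjusted over the list alone). p53 targets had a median log2 of -0.65 (adjusted p = 0.337, and adjusted p = 0.633 with an estimated correlation). The mean was 0.13, opposite in sign to the median.

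Markers of other cell types were mixed at day 21 against day 0, and bulk libraries do not show which cells expressed them. Mesothelial and epicardial markers diverged, mesothelin, Msln, rising by log2 4.33 ± 0.32 as keratin 19, Krt19, fell (log2 -4.63 ± 0.68). Of 9 such genes 1 was higher and 5 lower (1 and 5 adjusted over the list alone). Mesothelial markers had a median log2 of -0.77 (adjusted p = 0.10, and adjusted p = 0.622 with an estimated correlation). Pericyte and smooth muscle markers were 5 higher and 5 lower of 11 (5 and 5 adjusted over the list alone). Pericyte markers had a median log2 of 0.15 (adjusted p = 0.699, and adjusted p = 0.761 with an estimated correlation). Their mean of -0.34 and test direction were opposite in sign to the median. Schwann cell markers were 3 higher and 0 lower of 5 (3 and 0 adjusted over the list alone). Schwann cell markers had a median log2 of 0.76 (adjusted p = 0.158, and adjusted p = 0.474 with an estimated correlation). Of the cardiomyocyte markers 4 could be tested, too few for a list test, and all were higher, with Tnnt2 at log2 2.75 ± 0.21 and Ryr2, with 0 reads at day 0, at least 5.83-fold higher, while Myh6 had 0 reads in every library. The T cell gene Cd3e and the B cell gene Ms4a1 had 0 reads in every library as well, with the caution given for values of 0.

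Osteocyte genes beyond Dmp1 stayed at the edge of detection, Sost and Phex with 1 read at day 0, 1 at day 7 and 0 later, and Mepe with 0 throughout.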
